A study of Mus musculus with 6 samples.

How the data were processed

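Total RNA of RAW264.7 cells, a mouse macrophage line, was sequenced in 6 libraries, 3 from cells given 150 µg/ml of the extract C2S for 24 h and 3 PM_control libraries from cells given 0 µg/ml. Groups and replicate numbers were taken from the sample titles and treatment labels. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. Per the series design text, reads were trimmed with fastp, aligned to the mm10 mouse genome with STAR and counted per gene with RSEM, and the authors compared the groups with edgeR and tested KEGG pathways with clusterProfiler. Versions, the gene annotation and strandedness are not given in the sources used here, so overlap was counted on either strand, as the percent of a gene's exon length shared with the gene that overlaps it most. Named genes with at least 10% are given as uncertain in the report, and many others overlap by less.

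The authors deposited 1 table per library, with expected counts, TPM, FPKM, and gene and effective lengths per gene, per the file headers. Expected counts are RSEM's estimated reads per gene, with reads that map to several genes shared out by its model, per the file headers and values. The deposited TPM values are scaled for transcript length and for library depth, and the deposited FPKM values, which differ from TPM by 1 factor per library, were not used. Each table held 52636 genes, of which 52403 carried a symbol and 52489 were found in GENCODE M21 (GRCm38), the source of coordinates, exon numbers and GC content. Every column of values belonged to a named sample.

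Expected counts were rounded to whole numbers. Totals ranged from 8594485 to 10665869, and with a floor of 3 counts the smallest level that a library could show was between 0.281 and 0.349 CPM. Of the tested genes, 1245 (10.8%) had an expected count more than 0.005 from a whole number in some library, a sign of shared reads. Libraries of a group were checked for duplicates by a chi-square test of their counts over genes with at least 20 counts in a pair. Ratios of chi-square to degrees of freedom were 4.3 to 6.46 and no tables were identical, so each counted as 1 replicate.

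Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 11561 genes and 99.85% of all counts. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, R 4.3.3) with TMM normalization, the group as the only term and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 7.52%. Means and SDs are of TMM-scaled CPM, log2 fold changes are C2S over PM_control, and a 2-fold change is a filter on the fitted value. The SE of a log2 fold change is its size divided by the square root of the F statistic. It is therefore approximate, above all for genes with few counts in a group. A gene with 0 counts in a group was given a fold bound against 3 counts over that group, and one with 1 to 3 counts a ratio with an exact 95% counting interval.

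Lists of 41 gene groups, from textbook knowledge, the tests, the rule for named genes and all alternatives but the last 3 below were fixed before the data were examined. A list with at least 5 tested members was tested with camera at a preset correlation of 0.01 on voom values, with adjustment over the 37 lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives. Members called are given over all genes tested and, where different, adjusted over the list alone. Named genes had a symbol that is not a predicted-gene name, were called and had the 3 values of one group on one side of the other 3. They were the 8 largest fitted changes per direction with a mean of at least 5 CPM, the 4 smallest adjusted p per direction, up to 2 per direction and list by adjusted p, and 14 fixed readout genes whatever their p. Genes named outside that rule are said to be so, and some genes that the rule names are not reported here.

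Alternatives were RLE and upper quartile normalization, DESeq2, edgeR's exact test, limma-voom, limma on log2(TPM + 1) of genes with a mean TPM of at least 1, no low-count filter, at least 1 CPM in 3 libraries, unrounded counts, the replicate number as a block, leaving out the 10 most abundant genes, the mitochondrial genes or each library in turn, and a glmTreat test against 1.5-fold. Chosen after the data were seen were library sizes alone, leaving out genes with non-whole counts, and removing the trend over GC content fitted in each library on nuclear protein-coding genes.

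The tests were tried on simulated data for the comparison of C2S with PM_control. Over 11420 genes, 50 genes at each fold size were changed, and the recovered share was 72% at 1.5-fold, 88% at 2-fold and 100% at 4-fold and 8-fold, with 9 false calls (4.76% of calls). Over 11413 genes with no change simulated, 0 of 37 lists were called, by camera, where edgeR called 2 genes. Simulated genes were drawn independently of each other, so the list test was not tried on genes that move together. In the data the estimated correlation was 0.262 for the ribosomal protein list, the highest of the tested lists. It was 0.00625 for the autophagy list and -0.000114 for the ATF4 list. With a log2 change of 0.5 added to the autophagy genes, that list alone was called. A simulated difference of -0.5 between genes with few and many exons came back as -0.504, and the neighbour test over 33738 genes gave a ratio of 1.1 for random genes and 32.4 for planted ones.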

Results

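Transcript levels were measured by RNA sequencing in 6 libraries of RAW264.7 cells, a macrophage line from BALB/c mice. Cells of 3 libraries had received the extract C2S at 150 µg/ml for 24 h, and cells of the 3 PM_control libraries had received 0 µg/ml. The labels spell out neither name. The comparison asks which transcripts differed between macrophages kept with and without the extract. Total estimated counts were 10491307, 8594485 and 9132312 in the C2S libraries and 10665869, 9642784 and 9149574 in the controls. A floor of 3 counts in a library corresponded to between 0.281 and 0.349 CPM, the counts of a gene scaled to a common library total, and floors and counting intervals cover counting error only. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

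Libraries of one group resembled each other more than libraries of different groups. Spearman correlations of log2 CPM across 11561 genes, which are not independent replicates, were 0.992 to 0.995 within groups and 0.945 to 0.95 between them. The first principal component held 81.1% of the variance and separated the groups. The number of genes with any count was 16668, 15874 and 15900 with C2S, against 15067, 14660 and 14769 in the controls. The mitochondrial genome took 1.07%, 1.15% and 1.00% of counts with C2S and 1.57%, 1.48% and 1.43% in the controls.

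The transcription factor gene Jun and the growth factor gene Vegfa rose with C2S, while the chemokine receptor gene Cx3cr1 and the division marker Mki67 fell. Jun, a subunit of AP-1, rose from 35.9 ± 0.788 to 539 ± 23.6 CPM (SD, n = 3 per group), a log2 fold change of 3.91 ± 0.07 (SE; edgeR, adjusted p = 2.02e-16). Vegfa, which encodes an angiogenic growth factor, rose from 2.31 ± 0.357 to 156 ± 28.7 CPM, a log2 fold change of 6.07 ± 0.16 (edgeR, adjusted p = 1.62e-14). Cx3cr1, the receptor of the chemokine fractalkine, fell from 567 ± 39.7 to 109 ± 10.3 CPM, a log2 fold change of -2.38 ± 0.08 (edgeR, adjusted p = 1.34e-13). Mki67, a marker of dividing cells, fell from 657 ± 52.7 to 238 ± 16.9 CPM (edgeR, adjusted p = 2.98e-11).

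Of the 11561 genes tested, 6405 (55.4%) changed, with 3123 higher and 3282 lower with C2S. At least 2-fold changes numbered 1678, with 849 higher and 829 lower. In 61.1% of all tested genes the 3 C2S values lay on one side of the 3 control values, against 10% given by chance. The same held for 6147 of the changed genes (96%), a share raised by their selection on these same values. The higher genes made up 48.8% of the calls, but 35.9% with limma on log2(TPM + 1), where TPM is a length-scaled abundance, and 38.3% with library sizes alone as the scaling, a setting chosen after the data were seen.

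**Figure D1:**
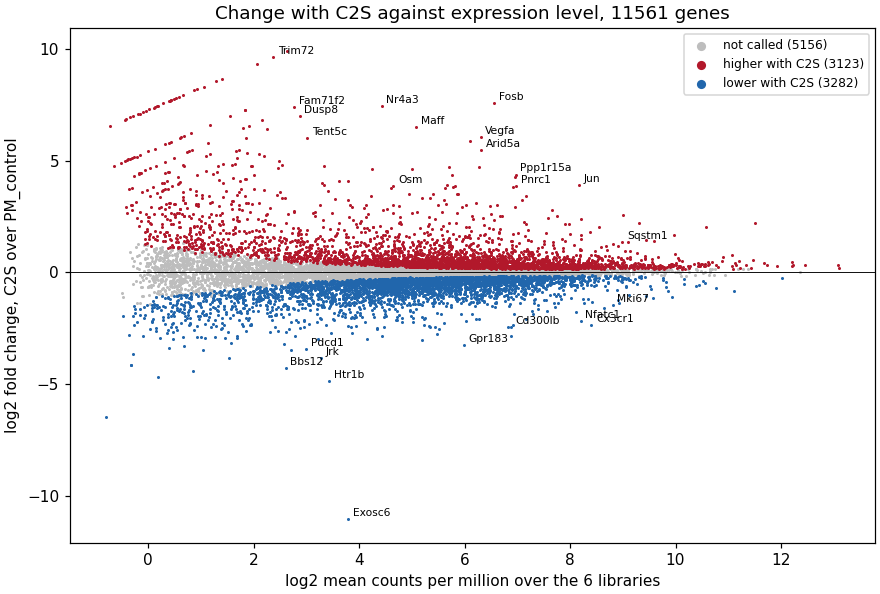
Log2 fold change of C2S over PM_control (vertical axis) against log2 mean CPM over the 6 libraries (horizontal axis), 1 point per gene for 11561 genes. Red points are the 3123 genes called higher, blue points the 3282 called lower and grey points the genes not called; the lines of points at the upper left are genes with few or no counts in the controls.

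The 8 largest rises by fitted fold change among genes with a mean of at least 5 CPM were those of Trim72, Fosb, Nr4a3, Fam71f2, Dusp8, Maff, Vegfa and Tent5c. Fosb (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051), another AP-1 subunit, went from 0.94 ± 0.378 to 188 ± 26.4 CPM (log2 fold change 7.60 ± 0.17). Nr4a3, an orphan nuclear receptor, had a log2 fold change of 7.46 ± 0.33, Maff, a small Maf transcription factor, one of 6.50 ± 0.18, and Tent5c, a poly(A) polymerase, one of 6.03 ± 0.40. Nr4a3 had 7, 0 and 0 control counts and Tent5c had 1, 0 and 6, so the size of their changes rests on few reads. Fam71f2 had 2 control counts in all and a CPM ratio of 193 (95% counting interval 53.1 to 1600), and Dusp8, a phosphatase of MAP kinases, had 3 and a ratio of 137 (46.7 to 669). Trim72 (ENSMUSG00000042828, chromosome 7, 128003949 to 128011033) had 0 control counts and was at least 101-fold higher, with the floor of 3 counts taken over the group. Its exons overlap Gm15533, so its value is uncertain. Maff lies 1.61 kb past the 3' end of Tmem184b. The smallest adjusted p-values among rises were those of Jun (ENSMUSG00000052684, chromosome 4, 95049034 to 95052222), Arid5a, Pnrc1 and Ppp1r15a, of which Arid5a, an RNA-binding protein that stabilises cytokine transcripts, had a log2 fold change of 5.49 ± 0.11.

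Among the 8 largest falls, Exosc6 had 0 counts with C2S and 27.8 ± 5.25 CPM in the controls, at least 270-fold lower, but it lies wholly within exons of Aars and its counts are uncertain. Log2 fold changes were -4.89 ± 0.33 for Htr1b, a serotonin receptor, -4.27 ± 0.29 for Bbs12, a chaperonin-like protein of cilia, -3.85 ± 0.20 for Jrk, -3.48 ± 0.26 for Spsb2, which directs inducible nitric oxide synthase to degradation, and -3.19 ± 0.28 for Ankrd34a. Pdcd1, the inhibitory receptor PD-1, was at -3.45 ± 0.24, and Gpr183, an oxysterol receptor that guides immune cell migration, at -3.26 ± 0.10, from 114 ± 8.38 to 11.9 ± 1.2 CPM. The smallest adjusted p-values among falls were those of Cd300lb, Fem1a, Gpr183 and Cx3cr1. The exons of Htr1b overlap D430036J16Rik over 18% of their length, so its value is uncertain, and those of Jun overlap Junos over 7.3%. Htr1b, Bbs12, Jrk, Gpr183, Ankrd34a and Fem1a have at most 2 exons, and nuclear protein-coding genes with 1 or 2 exons had a median log2 fold change of -0.48, against 0.06 with 10 or more.

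Of 41 gene lists fixed before the data were examined, 37 had at least 5 tested members and 16 shifted with C2S, 12 upward and 4 downward, in limma's camera test with a preset correlation between genes. The same test called 5 to 12 lists in each of the 9 other splits of the 6 libraries into 3 and 3. Those splits keep part of the difference between the groups, so they do not measure false calls. With a correlation estimated for each list, the ATF4 list alone passed. Among other named genes, exons of Bnip3 (22.3%), Txnip (19.4%), Cxcl16 (18.3%), Sqstm1 (17.3%), Mpo (15%), Atp5j (12.7%), Icam1 (11.7%) and Keap1 (10.9%) overlap another gene over the given part of their length, so their values are uncertain. The medians of the 16 lists kept their sign under every scaling and filter tried. The members called with adjustment over the list alone are given where they differ from the genome-wide counts, and they were the same for 31 lists.

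The immediate early and ATF4 lists had the medians farthest from 0 among the 16. Of 28 immediate early genes, 24 rose and 4 fell (median 2.26; camera, adjusted p = 4e-14; adjusted p = 0.202 with an estimated correlation). Atf3 rose by 4.27 ± 0.09 on the log2 scale, whereas Myc (-2.40 ± 0.33) and Egr3 (-1.05 ± 0.15) fell. Of 32 genes of the ATF4 and amino acid response, 28 rose and 0 fell (median 1.08; camera, adjusted p = 3.31e-15; adjusted p = 0.025 with an estimated correlation). Ppp1r15a, a subunit of the phosphatase that reverses eIF2α phosphorylation, rose from 11.5 ± 1.32 to 240 ± 15.4 CPM. Of 23 endoplasmic reticulum chaperone genes, 11 rose and 2 fell, or 11 and 3 adjusted over the list alone (median 0.14; camera, adjusted p = 0.0157; adjusted p = 0.302 with an estimated correlation). Herpud1 (2.15 ± 0.08) and Dnajb9 (2.96 ± 0.13) rose, while Xbp1, a transcription factor of the unfolded protein response, fell by 0.95 ± 0.06. Of 16 heat shock genes, 12 rose and 1 fell (median 0.59; camera, adjusted p = 0.000124; adjusted p = 0.302 with an estimated correlation). Bag3 rose by 1.23 ± 0.07 and Chordc1 fell by 0.60 ± 0.07, and Hspa1b (3.50 ± 0.25) shares reads with the near-identical Hspa1a and is uncertain.

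Genes of Toll-like receptor signalling fell more often than they rose, and cytokine genes moved both ways. Of 22 Toll-like receptors and adaptors, 13 fell and 5 rose (median -0.51; camera, adjusted p = 0.0495; adjusted p = 0.503 with an estimated correlation). Tlr2, a receptor of bacterial lipoproteins, fell from 246 ± 20 to 88.9 ± 13.3 CPM, Tirap fell by 1.78 ± 0.11 on the log2 scale, and Irak2 rose by 1.46 ± 0.09. That list missed the threshold with the replicate block (camera, adjusted p = 0.053), without C2S replicate 1 (0.0651), without C2S replicate 3 (0.0568) and without PM_control replicate 1 (0.0537). It also missed it with library sizes alone (0.067) and with the GC trend removed (0.0612), both chosen after the data were seen. Over its 14 alternatives the adjusted p ranged from 0.00361, with fry, to 0.503, with camera at an estimated correlation. Of 17 cytokines and chemokines, 8 rose and 5 fell (camera, adjusted p = 0.289). Osm, a cytokine of the interleukin-6 family, rose from 3.24 ± 0.361 to 46.9 ± 3.81 CPM, Tnfsf9 rose by 1.74 ± 0.11, and Cxcl16 (-0.64 ± 0.09) and Ptgs2 (-0.97 ± 0.16) fell. Tnf did not pass the test (40.2 ± 6.57 against 47.5 ± 5.14 CPM; edgeR, adjusted p = 0.0811), although it did without C2S replicate 1 (0.0104), without PM_control replicate 3 (0.0367), with the replicate block (0.0219) and without the low-count filter (0.0234). It also did with library sizes alone (0.0194) and with the GC trend removed (0.0195), both chosen later, and the adjusted p ranged from 0.0104 to 0.35 over its alternatives. Il1b had 3 counts with C2S and 0 in the controls and Il6 had 7 and 0, so both were below the count filter.

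Of 21 genes of NF-kB feedback and signalling, 10 rose and 5 fell (camera, adjusted p = 0.36), with Icam1 (1.24 ± 0.06) and Relb (1.06 ± 0.11) higher and Tnip3 (-2.28 ± 0.09) and Tnip1 (-1.02 ± 0.07) lower. Of 8 classical activation markers, 4 rose and 2 fell (camera, adjusted p = 0.532), among them Cd40, a co-stimulatory receptor (2.12 ± 0.25), and Acod1, which makes itaconate (-1.84 ± 0.25). Nos2, inducible nitric oxide synthase, went from 1.31 ± 0.514 to 3.36 ± 0.5 CPM (edgeR, adjusted p = 0.00384), a call lost on log2(TPM + 1) (limma, adjusted p = 0.0817; range over its alternatives 0.000276 to 0.0817). Of 8 alternative activation markers, 2 rose and 4 fell (camera, adjusted p = 0.763), with Klf4 at 1.17 ± 0.10 and Egr2 at -0.97 ± 0.18. Arg1 had 0 counts in every library, Mrc1 had 27 against 16 counts in all and Il10 had 2 against 5. Of 32 type I interferon response genes, 13 rose and 6 fell, or 14 and 6 adjusted over the list alone (camera, adjusted p = 0.11), with Stat2 (1.23 ± 0.10) higher and Ifi47 (-1.54 ± 0.30) lower. Of 14 inflammasome genes, 4 rose and 4 fell (camera, adjusted p = 0.983), where the median was -0.11 (0.03 with the GC trend removed) but the mean 0.35 and the test direction upward. Pycard, an inflammasome adaptor, had a log2 fold change of 5.31 ± 0.46 but overlaps Gm45205 and is uncertain, while Txnip fell by 0.73 ± 0.06. Pycard had 0, 1 and 5 control counts.

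**Figure D2:**
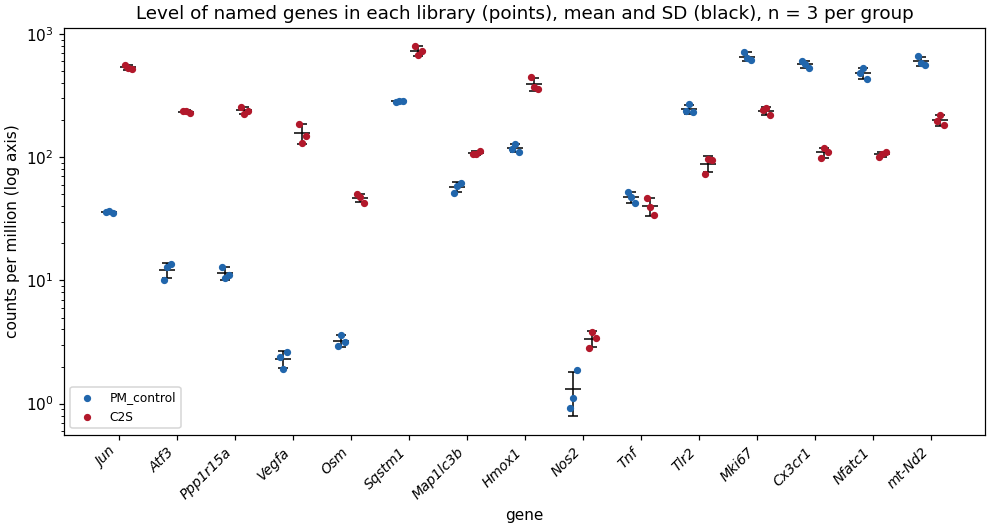
CPM (log axis) of 15 named genes in each library (points), with the mean and SD of each group of 3 in black, PM_control in blue and C2S in red. Jun, Atf3, Ppp1r15a, Vegfa and Osm lay higher in each C2S library than in each control library, and Tnf overlapped.

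Genes of autophagy and lysosomes rose. Of 43 autophagy genes, 28 rose and 5 fell (median 0.34; camera, adjusted p = 0.000116; adjusted p = 0.202 with an estimated correlation), although 16 were called higher on log2(TPM + 1). Sqstm1, the autophagy receptor p62, rose from 286 ± 2.5 to 732 ± 63.2 CPM, Ulk1, a kinase that starts autophagy, rose by 2.33 ± 0.08 on the log2 scale, and Atg16l1 fell by 0.91 ± 0.10. Map1lc3b rose by 0.92 ± 0.08, with shared reads that make it uncertain. Of 44 genes of lysosomes and the vacuolar ATPase, 31 rose and 4 fell, or 32 and 5 adjusted over the list alone (median 0.35; camera, adjusted p = 4.84e-06; adjusted p = 0.302 with an estimated correlation). Gla, a lysosomal galactosidase, rose by 2.21 ± 0.09 and Atp6v0a1 by 1.03 ± 0.08. Of 28 genes of mitophagy and mitochondrial dynamics, 4 rose and 10 fell (camera, adjusted p = 0.465), with Bnip3 at 1.16 ± 0.16 and Mfn2 at -0.36 ± 0.06. Of 25 NRF2 targets and regulators, 14 rose and 2 fell (median 0.25; camera, adjusted p = 0.00388; adjusted p = 0.263 with an estimated correlation), with Hmox1, heme oxygenase, going from 119 ± 8.22 to 391 ± 48 CPM and Keap1, which represses NRF2, at -0.89 ± 0.07. Of 17 iron handling genes, 8 rose and 4 fell, or 9 and 4 adjusted over the list alone (camera, adjusted p = 0.17), with Pcbp1 at -0.71 ± 0.05. Of 11 metallothioneins and zinc transporters, 5 rose and 6 fell (camera, adjusted p = 0.867), with a median of -0.28 but a mean of 0.13 and an upward test direction. Slc30a1, a zinc exporter, rose by 1.42 ± 0.09 and Slc30a5 fell by 0.55 ± 0.07.

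Protein-coding transcripts of the mitochondrial genome fell, and the list of nuclear respiratory genes did not pass the test. Of 12 protein-coding mitochondrial transcripts, 11 fell and 0 rose (median -1.05; camera, adjusted p = 2.26e-06; adjusted p = 0.302 with an estimated correlation). mt-Nd2 fell from 603 ± 52.5 to 200 ± 20.1 CPM and mt-Nd6 had a log2 fold change of -2.19 ± 0.10, while mt-Co1, named after its value was seen, was not called (0.02 ± 0.07). Of the mitochondrial ribosomal RNAs, which are outside the list and were named after their values were seen, mt-Rnr1 rose by 1.48 ± 0.10 and mt-Rnr2 fell by 0.76 ± 0.17. The call ended once the trend of each library over GC content was removed, a setting chosen after the data were seen (median -0.26; camera, adjusted p = 0.0668; range over its alternatives 3.19e-10 to 0.302), with 7 falling and 1 rising. Nuclear protein-coding genes in the tenth of lowest GC content had a median log2 fold change of -0.28 and those in the tenth of highest GC content one of 0.14. Of 76 nuclear genes of oxidative phosphorylation, 18 rose and 8 fell, or 12 and 6 adjusted over the list alone (camera, adjusted p = 0.485), with Cox4i1 at 0.31 ± 0.06 and Atp5j at -0.27 ± 0.07. Of 25 genes of the tricarboxylic acid cycle, 10 rose and 3 fell (camera, adjusted p = 0.171), with Pdhb at 0.63 ± 0.07 and Idh3a at -0.34 ± 0.06. Ppargc1a had 0 counts in every library.

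Of 32 genes of glycolysis and the hypoxia response, 21 rose and 3 fell, or 23 and 4 adjusted over the list alone (median 0.45; camera, adjusted p = 9.31e-06; adjusted p = 0.302 with an estimated correlation). Ndrg1, a hypoxia-induced gene, rose from 25.9 ± 1.34 to 246 ± 20.4 CPM, while Hif1a fell by 0.48 ± 0.07 on the log2 scale. Of 24 genes of cholesterol and isoprenoid synthesis, 12 rose and 2 fell (median 0.26; camera, adjusted p = 0.0159; adjusted p = 0.314 with an estimated correlation). Insig1, which holds sterol sensing in the endoplasmic reticulum, rose by 1.63 ± 0.09. Of 23 genes of fatty acid synthesis and LXR targets, 14 rose and 3 fell (median 0.28; camera, adjusted p = 0.0198; adjusted p = 0.322 with an estimated correlation). The cholesterol exporter genes Abca1 (1.99 ± 0.14) and Abcg1 (0.94 ± 0.08) rose, and Elovl6 (-1.10 ± 0.10), a fatty acid elongase, and Lpl (-0.82 ± 0.07) fell. On log2(TPM + 1), 7 genes of the cholesterol list and 8 of the fatty acid list were called higher.

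Genes of cell division fell. Of 40 genes of mitosis and G2/M, 29 fell and 1 rose (median -0.45; camera, adjusted p = 3.16e-08; adjusted p = 0.302 with an estimated correlation), with Cenpf, a kinetochore protein, at -1.84 ± 0.09 and Cdc25b at 0.37 ± 0.07. Of 42 genes of DNA replication and G1/S, 21 fell and 5 rose, or 22 and 5 adjusted over the list alone (median -0.20; camera, adjusted p = 0.0233; adjusted p = 0.302 with an estimated correlation). Gins3 fell by 1.52 ± 0.13 and Cdt1, a replication licensing factor, rose by 0.48 ± 0.06. Of 28 p53 targets and apoptosis genes, 10 rose and 9 fell, or 11 and 9 adjusted over the list alone (camera, adjusted p = 0.517), with a median of -0.003 (0.01 with RLE normalization) but a mean of 0.41 and an upward test direction. Sesn2 (3.42 ± 0.08) and Bcl2l11, which encodes the pro-apoptotic BIM (3.01 ± 0.08), rose, and Sesn1 fell by 1.73 ± 0.12.

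Of 77 ribosomal protein genes, 49 rose and 0 fell, or 51 and 0 adjusted over the list alone (median 0.20; camera, adjusted p = 2.26e-06; adjusted p = 0.431 with an estimated correlation), with Rpl10a, which shares reads, at 0.35 ± 0.06. Whole counts in every library were found for 15 of them, of which 11 rose, and the others may share reads with other genes and are uncertain. The genes called higher numbered 31 without C2S replicate 3, 7 on log2(TPM + 1), and 23 with library sizes alone and 28 with the GC trend removed, both chosen later. Of 32 genes of ribosome biogenesis and MYC targets, 7 rose and 12 fell (camera, adjusted p = 0.0932), with Rrs1 (-1.29 ± 0.06) and Ppan (-1.14 ± 0.06) lower and Nop14 (0.31 ± 0.06) higher. That list passed without the low-count filter (camera, adjusted p = 0.00371), and with library sizes alone (0.0286) and the GC trend removed (0.0336). Over its alternatives the adjusted p ranged from 0.000415, with fry, to 0.302, with camera at an estimated correlation. Of 31 proteasome genes, 7 rose and 6 fell (camera, adjusted p = 0.869), with Psmd4 at 0.48 ± 0.07 and Psma4, which shares reads, at -0.38 ± 0.06.

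No list of growth factor, calcium, osteoclast, matrix protease or cytoskeleton genes passed the camera test. With fry, the adjusted p was 0.00407 for growth factors, 0.0339 for matrix proteases and 0.0388 for cytoskeleton genes, all below the threshold. It was 0.86 for calcium genes and 0.706 for osteoclast genes. Of 13 bone-forming and angiogenic growth factors, 5 rose and 4 fell, or 5 and 5 adjusted over the list alone (camera, adjusted p = 0.627), with Vegfa and Osm among the rises and Pdgfb (-1.21 ± 0.07) and Vegfc (-2.03 ± 0.27) among the falls. Bmp2 had 1 count with C2S and 3 in the controls. Of 43 genes of calcium channels, pumps and calcium-dependent signalling, 15 rose and 14 fell (camera, adjusted p = 0.711), with the calcium release channels Itpr1 (0.96 ± 0.08) and Itpr2 (0.88 ± 0.08) higher and Nfatc2 (-1.52 ± 0.08) lower. Of 23 osteoclast differentiation genes, 7 rose and 7 fell (camera, adjusted p = 0.867). Nfatc1, the master transcription factor of osteoclasts, fell from 482 ± 49.1 to 106 ± 5.15 CPM and Tnfrsf11a, the receptor RANK, fell by 1.23 ± 0.08 on the log2 scale, while Clcn7 rose by 1.17 ± 0.08. Of 10 matrix proteases and inhibitors, 3 rose and 4 fell (camera, adjusted p = 0.868), with the urokinase gene Plau at -1.63 ± 0.08 and its receptor gene Plaur at 1.06 ± 0.09. Of 25 actin cytoskeleton and adhesion genes, 11 rose and 6 fell (camera, adjusted p = 0.168), with Zyx at 1.61 ± 0.11 and the integrin gene Itga5 at -1.20 ± 0.07.

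Of 14 antigen presentation genes, 11 rose and 0 fell (median 0.51; camera, adjusted p = 0.000235; adjusted p = 0.215 with an estimated correlation), or 7 on log2(TPM + 1). Cd74, the invariant chain of class II molecules, rose from 437 ± 21.2 to 803 ± 52.4 CPM. The 6 other members were below the count filter, among them the class II genes H2-Aa, H2-Eb1 and H2-Ab1. These had at most 1, 1 and 6 counts in a library, so the rise of the list does not cover them. Of 17 macrophage identity markers, 8 rose and 2 fell (camera, adjusted p = 0.485), with Laptm5 at 0.42 ± 0.06 and Cd14 at -0.60 ± 0.06. Of 21 phagocytic and scavenger receptors, 7 rose and 6 fell (camera, adjusted p = 0.627), with a median of 0.18 and an upward test direction but a mean of -0.03. Mfge8 rose by 0.66 ± 0.06 and Colec12 fell by 0.59 ± 0.06. Markers of other cell types were too few above the filter for a list test. Of the epithelial and endothelial markers, 3 were tested and 2 rose: Pecam1 (4.83 ± 0.51), which lies 29.7 kb past the 3' end of Ddx5, and Egfl7 (0.93 ± 0.35). Pecam1 had 2, 1 and 3 control counts. Egfl7 lost its call without C2S replicate 2 (edgeR, adjusted p = 0.115), C2S replicate 3 (0.0634), PM_control replicate 1 (0.1247) or PM_control replicate 3 (0.0822). It also lost it with DESeq2 (0.121), with limma on log2(TPM + 1) (0.535), without the low-count filter (0.0615) and, in settings chosen later, with library sizes alone (0.0515) or the GC trend removed (0.0843), and the range over its alternatives was 0.0174 to 0.535. The neutrophil, mast cell and dendritic cell list had 1 tested gene, Mpo, which had 0 control counts, was at least 18.8-fold higher and lies 50 kb past the 3' end of Supt4a. Both tested lymphocyte markers rose, Ighm by 0.53 ± 0.08 and Lck by 0.88 ± 0.30, of which Lck lost its call without C2S replicate 3 (edgeR, adjusted p = 0.0546), PM_control replicate 2 (0.0859) or PM_control replicate 3 (0.0644) and with DESeq2 (adjusted p = 0.0697), with a range of 0.007 to 0.0859 over its alternatives. Of 2 tested markers of osteoblasts, fibroblasts and mesenchymal cells, Tagln rose (1.76 ± 0.33) but overlaps Gm48529. The untested markers of these 4 lists reached at most 2.16 CPM, in Cd79a.

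**Figure D3:**
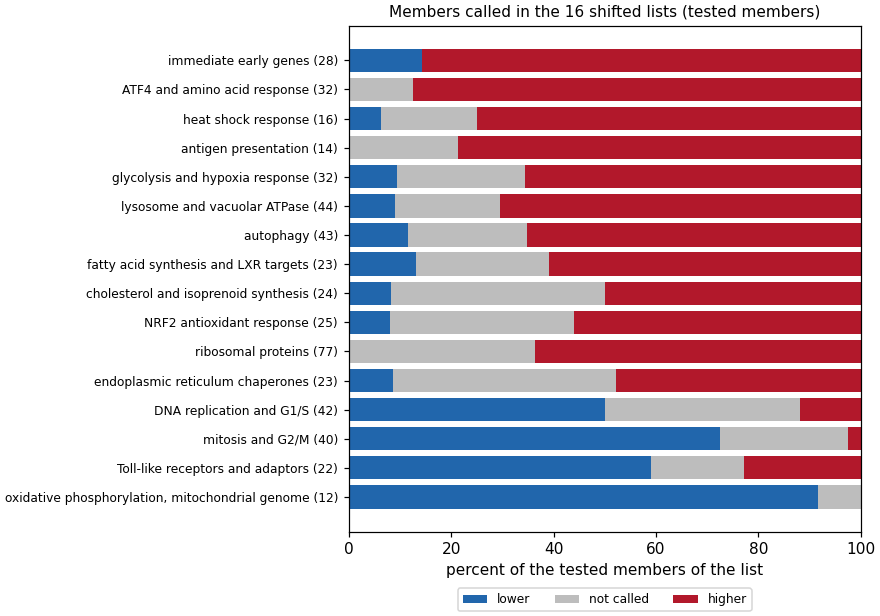
Percent of the tested members of each of the 16 shifted lists (number tested in brackets) that were called higher (red), lower (blue) or not called (grey). All 28 called members of the ATF4 list were higher, and all 11 called protein-coding transcripts of the mitochondrial genome were lower.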

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

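The settings with library sizes alone, without genes with non-whole counts and with the GC trend removed were chosen only after the results were seen. The number of changed genes was 6405, between 4782 and 7084 under the alternatives and between 5901 and 6338 with 1 library left out. With 1 library left out, 2920 to 3150 genes were higher, 2981 to 3188 were lower, 1699 to 1813 had changed at least 2-fold and 15 to 16 lists had shifted. With limma on log2(TPM + 1), 1717 genes were higher in place of 3123, and the cause was not tested; the median of all genes moved by -0.1 there and by -0.09 with library sizes alone. Of the 16 shifted lists, 1 passed with camera at an estimated correlation. The autophagy list had an estimate of 0.00625, below the preset 0.01, yet its camera adjusted p moved from 0.000116 to 0.202. That of the ATF4 list, at -0.000114, moved from 3.31e-15 to 0.025. A correlation above the preset therefore does not account for these changes. With simulated independent genes, the raised autophagy list moved from 8.1e-96 to 0.00309 (camera, adjusted p). For the other lists the cause was not tested. Fry, which does not compare a list with other genes, called 29, of which the main test had not called 13. The first principal component held 62.9% of the variance on log2(TPM + 1), and the cause was not tested. Of 3327 values of 159 named genes, 3287 kept their direction and side of the threshold, 32 lost the call, 6 gained it and 2 reversed. The reversals came with the GC trend removed, for Ireb2 (0.045; edgeR, adjusted p = 0.557, range over its alternatives 9.23e-07 to 0.557) and Psma2 (0.034; edgeR, adjusted p = 0.686, range 0.000162 to 0.686), and beyond that trend the cause was not tested. Of the 6405 calls, 5262 were kept with the GC trend removed and 14 reversed, and of the 6189 that limma on log2(TPM + 1) tested, 4318 were kept and 5 reversed. With the replicate block, 6489 genes changed and 15 lists shifted. The call of the Toll-like receptor list was lost, that of Tnf gained, and no other list or gene named by the rule changed its call. Same-numbered samples correlated at -0.0112, 0.0686 and 0.0344 in their deviations from the group means. Replicates 2 and 3 of C2S correlated best with their own number, and replicate 1 did not. Values this near 0 do not decide whether the numbers pair the samples. At the depth, spread and replicate number of C2S against PM_control, 72% of simulated 1.5-fold changes among 11420 genes were recovered. The simulation changed 50 genes at each fold size, against 6405 called in the data, so its adjustment was stricter. The share recovered in the data may therefore differ, and which of depth, spread, replicate number or adjustment limits it was not tested.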

Other observations

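The gene families in the next paragraphs, the ribosomal RNA test and the subtraction of the GC trend for mitochondrial transcripts, and the comparison of ATF4 targets with other stress genes were chosen only after the results were seen. The neighbour test followed from seeing gained genes close to an expressed gene, with its bounds written before it was run. Since the families were picked for their values, no list test is given for them. Of 15 tested genes of the core clock and its outputs, 10 rose and 1 fell, with a median log2 fold change of 1.08. Ciart rose from 1.38 ± 0.564 to 23.1 ± 2.1 CPM (SD, n = 3 per group; edgeR, adjusted p = 1.41e-10), Bhlhe40 by 3.02 ± 0.10 (SE) on the log2 scale, Nfil3 by 2.72 ± 0.11 and Per1 by 1.73 ± 0.08, whereas Clock fell by 0.23 ± 0.10. The fall of Clock is uncertain, since 0 clock genes were called lower with RLE normalization, DESeq2, limma on log2(TPM + 1) or the replicate block. The same held with the GC trend removed and without C2S replicate 1 or 3 or PM_control replicate 1 or 3. Dual-specificity phosphatases, which switch off MAP kinases in many cases, rose in 11 of 18 tested members and fell in 4 (median 1.203, or 0.46 on log2(TPM + 1)). Dusp4 went from 95.4 ± 4.99 to 493 ± 19.5 CPM, and Dusp1, Dusp2, Dusp4, Dusp5 and Dusp6 also belong to the immediate early list.

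Of 260 tested zinc finger genes of the Zfp series, 142 were lower and 28 higher (median -0.58, and -0.51 with the GC trend removed). Of 35 zinc finger and BTB genes, 22 were lower and 3 higher (median -0.54). Polr2a, the largest subunit of RNA polymerase II, rose from 599 ± 32.7 to 2451 ± 91.3 CPM (log2 fold change 2.03 ± 0.07; edgeR, adjusted p = 1.53e-13), while 4 of the 12 tested subunits fell and 7 were not called. Against the ATF4 list's median of 1.08, endoplasmic reticulum chaperones had a median of 0.14 with an interquartile range of 0.34, and 10 tested targets of hypoxia-inducible factors had a median of 0.46 with one of 0.94, 6 of them higher and 0 lower by edgeR. Those 10 leave out the hypoxia-linked genes Vegfa (6.07 ± 0.16) and Ndrg1 (3.25 ± 0.08), which lowers their median, so the 2 medians do not rank the responses.

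The 6 libraries can be split into 3 and 3 in 10 ways, so the share of splits with a result as large cannot be under 0.1. The real split was the 1 split of 10 with a result as large for the genes changed (6405), higher (3123), lower (3282) and changed at least 2-fold (1678) and for the lists shifted (16). The other splits called at most 0 genes by edgeR and 0 by limma-voom, with 35 to 186 genes at an unadjusted p under 0.05 by edgeR. For lists, each of the 9 other splits called 5 to 12 with the preset correlation, although it called 0 genes. These splits put unequal numbers of C2S libraries on their sides, so part of the difference between the groups remains in them. Mixing the groups also widens the spread within a side, which lowers the number of genes called. The splits therefore measure false calls of neither lists nor genes.

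Nuclear protein-coding genes with 1 or 2 exons fell with C2S: of 559, 280 were lower and 108 higher. The difference of their median from that of 5238 genes with 10 or more exons was -0.54 (bootstrap 95% interval over genes -0.627 to -0.407). It had the same sign in 9 of 9 pairs of a C2S and a control library. These pairs reuse the same 6 libraries, so they are not independent. Genomic DNA in the control libraries was argued against, since the control excess in read density over silent olfactory receptor genes was -0.0231% of the median fall of the called genes. So was gene length or GC content, since the slope of log2 fold change on log2 exon number was 0.127 (0.104 to 0.151) with length, GC content and expression in the regression and 0.084 without. Reads shared with overlapping genes were argued against too, since the difference was -0.661 (-0.836 to -0.498) over genes with no overlap and whole counts. An effect of C2S on transcripts with few introns may remain as a hypothesis; RNA quality and the selection of RNA were not tested.

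Protein-coding transcripts of the mitochondrial genome fell by a median of 1.05 on the log2 scale, and scaling was argued against, since the median was still -1.035 under the scaling that brought it closest to 0. A loss of all mitochondrial RNA alike was argued against under the bound used by mt-Rnr1 alone, which rose by 1.48 ± 0.10, whereas mt-Rnr2 fell by 0.76 ± 0.17. The bound was changed from both ribosomal RNAs to either one after these values were seen. With both required, the test would have decided nothing. In the controls mt-Rnr1 and mt-Rnr2 were at 122 and 130 CPM, against 5219 CPM for mt-Co1. The selection of RNA was not tested, and a change in it cannot be told apart from theirs, so mt-Rnr1 does not settle the question. GC content stays open: the tenth of nuclear genes with the lowest GC had a median of -0.284, between the bounds set, and the mitochondrial median was -0.225 (-0.741 to 0.114) once the nuclear trend was subtracted, just past a bound of -0.25. The 496 nuclear protein-coding genes in the GC range of the mitochondrial ones had a median of -0.377. The fitted nuclear trend at the median mitochondrial GC was -0.608. With the trend removed in every library, the quartiles of the mitochondrial list moved from -1.17 and -0.49 to -0.76 and 0.04. Its median moved to -0.26 and its call ended. Whether the median or the spread of the members decided that was not tested. GC content and the treatment cannot be told apart here, since the low-minus-high GC difference was -0.242 to -0.531 in pairs of libraries across groups and at most 0.174 in size within them.

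Of 38318 genes with at most 3 counts over the controls, 623 had at least 10 with C2S, of which 425 are protein-coding, against 130 genes the other way. Sequencing depth was argued against, since after thinning to 1 total the lowest C2S library still had 1029 more genes above 0 than the highest control. Genomic DNA in the C2S libraries was argued against, since read density rose over silent olfactory receptor genes by 4.77% of its rise over all such low genes. Among genes that overlap no expressed gene, 57.9% of the 516 gained and 8.37% of the others lay within 20 kb past a 3' end of an expressed gene, with an odds ratio 3.63 times (2.82 to 4.81) that for lying before a 5' end; of the 88 genes lost the other way, 20.5% lay past a 3' end, so part of the enrichment occurred without a gain with C2S. Reads running past the ends of expressed genes may therefore account for part of the gain, and whether this follows from C2S or from the libraries was not tested.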
